A study of Arabidopsis thaliana and Arabidopsis lyrata and Arabidopsis thaliana x Arabidopsis lyrata with 3 samples.

How the data were processed

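Leaf RNA of Arabidopsis thaliana, of its relative A. lyrata and of the F1 hybrid between them was profiled by pyrosequencing of tags, with 1 library each. Per the labels, total RNA was isolated with Trizol. The deposited values are read counts: each of the 3 tables lists the distinct read sequences of 1 library with the number of reads that had exactly that sequence, with no header, no gene name and no alignment. Adapters, trimming, quality filters, base calling and the enzyme that cut the cDNA are not given in the sources used here. Of the reads, 98.4% (A. thaliana), 98.1% (A. lyrata) and 98.6% (hybrid) began with CGA. The 4-base site TCGA occurred inside 1.18%, 1.19% and 1.22% of the tag reads. Each tag was therefore treated as a sequence that starts at a fixed cut site of its transcript.

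No reference sequence of either genome was used here, so tags are reported by sequence and count and no gene is named. The 23 gene lists with 325 genes that were fixed before the data were examined, among them the lists of cell type markers, could not be matched to tags and gave no result. A setting with nuclear genes alone could not be run for the same reason.

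Reads that began with CGA and had at least 40 bases were kept as tag reads (206673, 149938 and 216299 reads, over 97.7% of each library). The tag reads of each parental library were clustered greedily, the most frequent sequence first, at 95% identity over the first 100 bases (edlib 1.3.9.post1, Python 3.11.15), and clusters of at least 3 reads were kept as tags, 7541 in A. thaliana and 7553 in A. lyrata. Tags of both species were paired as reciprocal best hits of blastn (BLAST+ 2.17.0, word size 11), with an alignment that began within 5 bases of both tag starts and covered at least 40 bases, which gave 2551 pairs. Pairs under 85% identity and the 82 pairs whose second hit scored over 95% of the best were left out, which left 2109. Their median identity was 92.9% (quartiles 90.0% and 95.5%). Tag pairs are numbered by their reads in the 3 libraries together, so tag pair 1 had the most. Every tag read was then matched to its nearest tag at 92% identity or more. Reads equally near to tags of several pairs were left out. In the hybrid, a read was assigned to the allele with the smaller edit distance over up to 150 bases. Alleles counted as assignable in the 1820 pairs with at least 3 reads in each parent and at least 95% of the parental reads assigned to their own species. The settings of clustering, pairing and read assignment were chosen after the reads had been seen. The allele comparison was first run over 100 bases and was extended to 150 because pairs that differ only beyond base 100 gave ties. For a check, tags were rebuilt from a random part of the parental reads and the remaining reads were assigned. Of these held-out reads, 0.0298% of the A. thaliana reads and 0.0289% of the A. lyrata reads went to the wrong allele in 1164 pairs. Held-out reads came from the same libraries as the tags, and copies of 1 sequence could fall in both parts. The check therefore does not cover hybrid reads whose sequence differs from that of the parental library.

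Library totals were the reads in used tag pairs (92450, 57050 and 87896), and levels are reads per 100000 of these. A count of 0 allows up to 3 reads, which is 3.25, 5.26 and 3.41 reads per 100000 in the A. thaliana, A. lyrata and hybrid libraries. For the species ratio, an exact binomial test set the reads of a tag pair in both parental libraries against the library totals. For the hybrid against the mean of the parents, the deeper parent was thinned at random to the depth of the other before the exact binomial test. For the allele share, hybrid reads of both alleles were tested against 50% by an exact binomial test. For the parental ratio against the allele ratio, a two-sided Fisher exact test with depth-scaled odds was used. P-values were adjusted by the Benjamini-Hochberg method over the pairs tested, those with at least 10 reads in the contrast. Calls needed an adjusted p under 0.05 and, in the first 3 contrasts, a ratio of at least 2-fold. Log2 ratios have a pseudocount of 0.5 reads. Intervals are exact Clopper-Pearson or Poisson intervals at 95% and cover counting error only, because PCR copies of 1 molecule cannot be told from separate molecules. With 1 library per group the tests compare libraries, not species or genotypes, and the differences have no replicate check. A low count of a tag in 1 species does not show that its gene was low, since another start site or a more distant copy of the gene would give another tag.

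Named tag pairs follow a rule set before the data were examined: in each contrast the 10 highest and 10 lowest ratios among called pairs with at least 50 reads (for the parental against the allele ratio, assigned reads of the parents and of the hybrid each), and the 10 pairs with most reads in each library. The planned rule spoke of genes and was applied to tag sequences. The contrasts, their thresholds and the alternatives were also set before the data were examined. The alternatives were TMM scaling (edgeR 4.0.16) and median-of-ratios scaling (DESeq2 1.42.0), other read minimums, identity minimums of 90% and 80%, shared reads split between pairs, each distinct sequence counted once, allele assignment from identical sequences or from 3 net differences, an expected share set to the overall share, and other fold thresholds. The contrasts were tested on simulated data, in which 200 of the pairs were changed by known folds per contrast. Counts were drawn from Poisson distributions, with no PCR copies, no spread between libraries and no wrongly paired tags. For the species ratio (1773 pairs tested), 52.0% of the 4-fold and 17.0% of the 2-fold changes were called. For the hybrid against the parents (2016 pairs) these shares were 69.0% and 22.0%, for the allele share (1180 pairs) 53.0% and 11.0%, and for the parental against the allele ratio (1141 pairs) 34.0% and 9.0%. Among the unchanged pairs of each simulation, 1 or 2 were called. This covers counting error alone and does not give the rate of false calls in the real libraries. With at least 50 reads, 55.6%, 39.1%, 36.0% and 33.3% of the 2-fold changes were called in these 4 contrasts. For 4-fold changes these shares were 97.4%, 100%, 100% and 85.2%. Many changes of 2-fold were thus missed. Depth limited the calls, and the first 3 contrasts also required an observed ratio of at least 2-fold.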

Results

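The data were the distinct pyrosequencing reads of 3 leaf libraries with their frequencies, from A. thaliana, from A. lyrata and from their F1 hybrid, each a group of 1. The A. thaliana library held 210426 reads of 150044 distinct sequences, the A. lyrata library 153345 reads of 111882 sequences and the hybrid library 219868 reads of 160854 sequences. The median tag read was 153, 155 and 152 bases long. The most frequent sequence took 1.04%, 1.06% and 0.739% of the reads. By its title, the series quantified allele-specific expression, and the design allows 4 questions: how tag levels differed between the species, how the hybrid stood to its parents, how hybrid reads divided between the parental alleles, and whether the ratio between the species returned between the alleles. Of the hybrid reads matched to a parental tag, 48.0% were nearest to an A. thaliana tag and 50.3% to an A. lyrata tag. In the A. thaliana library 97.9% of the matched reads were nearest to A. thaliana tags, and in the A. lyrata library 97.4% were nearest to A. lyrata tags.

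Tag pair 1 led all 3 libraries. It begins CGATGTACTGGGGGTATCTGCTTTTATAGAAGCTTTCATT in A. thaliana and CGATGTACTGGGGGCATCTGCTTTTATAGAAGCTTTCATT in A. lyrata, and the species differed in 131 compared bases by the substitutions T15C, A97G and A114C (A. thaliana base first, positions counted from 1 at the tag's start) and by 2 gap bases. Its first bases form an open reading frame in both species, read as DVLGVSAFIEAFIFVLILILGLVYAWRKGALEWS in A. thaliana. It had 5919 reads in A. thaliana (6402 per 100000, interval 6240 to 6568), 3365 in A. lyrata (5898, 5701 to 6101) and 4169 in the hybrid (4743, 4600 to 4889). The next pairs by total reads were tag pair 2 (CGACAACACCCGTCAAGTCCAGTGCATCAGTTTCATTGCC), with 1029, 2361 and 1916 reads per 100000 in A. thaliana, A. lyrata and the hybrid, and tag pair 3 (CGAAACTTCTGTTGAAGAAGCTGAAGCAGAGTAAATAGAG), with 1573, 889 and 1910 reads per 100000.

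Between the species, some tags with many reads in 1 library were nearly absent from the other. Tag pair 4 (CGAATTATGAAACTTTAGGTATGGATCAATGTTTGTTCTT) was the second most read tag pair of A. thaliana, with 2104 reads against 8 in A. lyrata, a log2 ratio of 7.26 (interval 6.36 to 8.56). Tag pair 110 (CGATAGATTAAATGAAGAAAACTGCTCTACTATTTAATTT) stood at the other end, with 3 reads in A. thaliana and 345 in A. lyrata (log2 -7.32, interval -9.83 to -5.98). With each distinct sequence counted once, the log2 ratio of tag pair 4 was 5.71 and that of tag pair 110 was -5.57. Other tag pairs far higher in A. thaliana were 81 (357 reads against 3), 108 (327 against 3), 124 (235 against 4), 177 (222 against 5), 105 (346 against 10) and 40 (496 against 16). The tag pairs 285, 197 and 341 closed the 10 highest, with log2 ratios of 4.02, 4.02 and 3.48. Far higher in A. lyrata were tag pairs 68 (5 against 275), 86 (6 against 309), 164 (3 against 160), 292 (4 against 128), 333 (5 against 118) and 67 (13 against 279), then 382, 281 and 369, whose log2 ratios were -4.92, -4.84 and -4.47. Among the most read pairs, tag pair 10 (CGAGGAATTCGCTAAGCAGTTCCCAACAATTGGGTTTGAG) was 4.25-fold higher in A. thaliana and tag pair 6 was 3.19-fold higher there, while tag pairs 2 and 26 were 2.29-fold and 2.58-fold higher in A. lyrata. Tag pair 26 was not called with each distinct sequence counted once (log2 -0.84). Tag pairs 7 and 11 had log2 ratios of -0.09 (interval -0.24 to 0.06) and -0.13 (-0.29 to 0.04), which counting error alone can give.

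Of 1841 tag pairs tested, 484 (26.3%) were apart between the parental libraries by the exact binomial test with Benjamini-Hochberg adjustment. The direction of these calls depended on the scaling and on the read minimum. With library totals, 178 were higher in A. thaliana and 306 in A. lyrata. With TMM factors 234 of 464 were higher in A. thaliana and 230 in A. lyrata, and with median-of-ratios factors these numbers were 250 and 215 of 465. These scalings moved the median log2 ratio of all tested pairs, -0.24 under library totals, by 0.24 and 0.30. They turned the ratios of tag pairs 7 and 11 positive (0.15 and 0.11 with TMM factors) and took tag pair 2 below the 2-fold threshold. With library totals and at least 50 reads, 120 of 230 calls were higher in A. thaliana and 110 in A. lyrata.

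The hybrid differed from the mean of its parents in fewer tag pairs. Tag pair 501 (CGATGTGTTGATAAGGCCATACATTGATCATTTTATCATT) was highest, with 62 hybrid reads against 16 and 8 in A. thaliana and A. lyrata, a log2 ratio to the parental mean of 2.12 (interval 1.38 to 3.01). Tag pair 660 (45 reads against 14 and 5) followed at 2.03, and tag pairs 637, 670, 198 and 57 lay between 1.65 and 1.78. Tag pair 57 (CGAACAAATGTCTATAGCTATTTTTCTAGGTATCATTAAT) had the most reads of these, with 441 per 100000 in the hybrid against 255 in A. thaliana and 24.5 in A. lyrata. Tag pairs 366, 521, 703 and 280 closed the 10 highest, at 1.60, 1.55, 1.54 and 1.47. At the low end, tag pair 632 (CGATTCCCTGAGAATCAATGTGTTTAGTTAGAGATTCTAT) kept 3 hybrid reads against 17 and 47 in the parents (log2 -3.68, interval -6.12 to -2.17) and tag pair 519 kept 5 against 44 and 34 (-3.12, -4.79 to -1.80). Several low tags were those with the strongest species ratios. Tag pair 110 fell from 605 reads per 100000 in A. lyrata to 42.1 in the hybrid, tag pair 292 from 224 to 21.6 and tag pair 333 from 207 to 10.2. Tag pair 105 fell from 374 in A. thaliana to 44.4 in the hybrid and tag pair 177 from 240 to 18. The 10 lowest ended with tag pairs 761, 706 and 645, at -2.09, -1.97 and -1.84.

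Of 2045 tag pairs tested against the mean of the parents, 117 (5.72%) were apart by the exact binomial test, 43 higher and 74 lower in the hybrid. In 22 of them the hybrid was at least 2-fold above both parents and in 37 at least 2-fold below both. With TMM factors the numbers were 62 higher and 63 lower, and with median-of-ratios factors 59 and 63. With no fold threshold 123 were higher and 109 lower, and at 4-fold or more 3 were higher and 35 lower. Counting each distinct sequence once gave 72 calls, and tag pairs 333, 637, 645 and 706 were not called under it.

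Within the hybrid, both alleles were seen at similar levels in many tag pairs, and 1 allele was nearly alone in a few. Tag pair 57 had 387 reads of the A. thaliana allele and 0 of the A. lyrata allele, at least 129-fold more when 0 is set to the floor of 3 reads. Tag pairs 320 and 305 likewise had 59 and 55 A. thaliana reads and no A. lyrata read, at least 19.7-fold and 18.3-fold more. Tag pair 40 had 424 reads to 1 (99.8% A. thaliana, interval 98.7% to 100%), tag pair 4 had 940 to 3 (99.7%, 99.1% to 99.9%), tag pair 35 had 415 to 3 (99.3%, 97.9% to 99.9%), tag pair 198 had 133 to 1, tag pair 29 had 485 to 5, tag pair 280 had 91 to 1 and tag pair 102 had 138 to 2. The A. lyrata allele was nearly alone in tag pair 281, with 73 reads to 0 (at least 24.3-fold), tag pair 67, with 293 to 4 (1.35% A. thaliana, interval 0.368% to 3.41%), tag pair 162, with 89 to 1 (1.11%, 0.0281% to 6.04%), and tag pair 86, with 122 to 2. Tag pairs 369, 164, 215, 254, 122 and 88 completed the 10 lowest, with A. thaliana shares of 1.85%, 3%, 6.52%, 10.9%, 11.7% and 14.2%. At a minimum of 90% identity, 6 of the 20 extreme allele pairs had no value, tag pairs 4 and 67 among them. Tag pair 1 drew 3868 of its hybrid reads from the A. thaliana allele and 300 from the A. lyrata allele (92.8% A. thaliana, interval 92% to 93.6%). In contrast, tag pair 7 had 521 and 484 reads (51.8%, 48.7% to 55.0%), tag pair 16 had 357 and 360, and tag pair 15 had 361 and 375, and none of these 3 differed from equal shares.

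**Figure D1:**
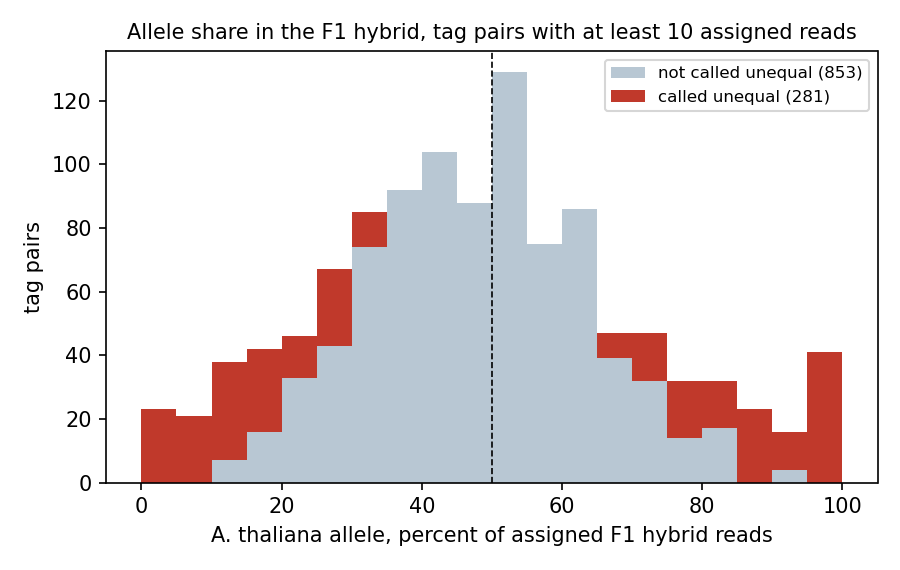
The histogram shows the percentage of assigned hybrid reads that carried the A. thaliana allele (x axis) against the number of tag pairs (y axis), for the 1134 tag pairs with at least 10 assigned reads. Red bars are the 281 tag pairs called unequal and the dashed line marks 50%; the median lies at 46.9%, with a separate peak of pairs near 100%.

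Of 1134 tag pairs tested, 281 (24.8%) had unequal alleles by the exact binomial test, 132 with more A. thaliana reads and 149 with more A. lyrata reads. When the expected share was set to the overall share of the tested pairs, 96 of 341 calls were to A. thaliana and 245 to A. lyrata. With at least 50 reads the direction turned, with 64 of 105 calls to A. thaliana and 41 to A. lyrata. The median share of the A. thaliana allele was 46.9% (interval 45.6% to 49.2%), with quartiles of 32.5% and 62.1%. Over all reads in assignable pairs, 43065 were A. thaliana and 35095 A. lyrata (55.1% A. thaliana), and without tag pair 1 the A. thaliana share was 53.0%. Among the 463 pairs with at least 30 assigned reads, 17 were at least 97% A. thaliana and 9 were at least 97% A. lyrata. Without a reference, tags of single nuclear genes could not be told from tags of plastids, of mitochondria or of the repeated genes of ribosomal RNA, whose shares in a hybrid are not those of 1 nuclear gene. This holds for tag pairs 1 and 162 and for the other one-sided pairs.

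The ratio between the parental libraries and the ratio between the alleles went together across tag pairs, with exceptions that were large. Tag pair 172 (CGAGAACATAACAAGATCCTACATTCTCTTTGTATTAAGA) had fewer reads in A. thaliana (42) than in A. lyrata (78), yet 129 of its 131 assigned hybrid reads were A. thaliana, a difference between the log2 allele and parental ratios of 7.28 (SE 0.96, from counting). Its alleles were told apart by the substitution T46A (A. thaliana base first, positions counted from 1 at the tag's start) and 2 gap bases in 68 compared bases. It had no value when at least 3 net differences were required. Tag pairs 35, 60, 134 and 198, with 2 substitutions each, had none either. With so few differences, a hybrid read whose sequence differs from the parental library could be given to the wrong allele. The held-out check does not cover this. Tag pair 134 moved from 18.0% A. thaliana in the parents, on the depth-scaled reads, to 89.1% in the hybrid, tag pair 181 from 34.0% to 94.7%, and tag pair 91 from 6.91% to 68.5%. Tag pairs 198, 29, 35, 33 and 57 moved further toward A. thaliana from parental shares of 80.3%, 79.8%, 84.3%, 59.0% and 91.2%, to hybrid shares between 96.2% and 100%, and tag pair 348 moved from 51.6% to 96.3%. Tag pair 177, with 16 assigned hybrid reads, moved furthest toward A. lyrata of the named pairs, by -6.59. Among pairs with at least 50 assigned reads in the parents and at least 50 in the hybrid, the limit of the naming rule, the largest such move was that of tag pair 162 (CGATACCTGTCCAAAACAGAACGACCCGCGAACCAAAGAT), whose parental share of 41.1% A. thaliana became 1.11% in the hybrid. Tag pair 118 (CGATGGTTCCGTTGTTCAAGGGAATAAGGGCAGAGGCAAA) had a parental share of 80.8% A. thaliana and near equal alleles, 61 and 66 reads, in the hybrid. Tag pairs 60, 370, 179, 64 and 48, with parental shares between 64.1% and 73.5%, also had hybrid shares of 43.1% to 51.1%. Tag pair 6 went from 76.2% to 59.7%, tag pair 122 from 28.6% to 11.7% and tag pair 215 from 23.1% to 6.52%. Among the pairs with most reads in a library, tag pairs 26, 1, 10, 2 and 3 differed toward A. thaliana, by 3.98, 3.57, 3.48, 0.64 and 0.36. Besides tag pair 6, tag pairs 8, 13 and 11 differed toward A. lyrata, by -0.78, -0.63 and -0.57. With each distinct sequence counted once, tag pairs 3 and 13 were not called.

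**Figure D2:**
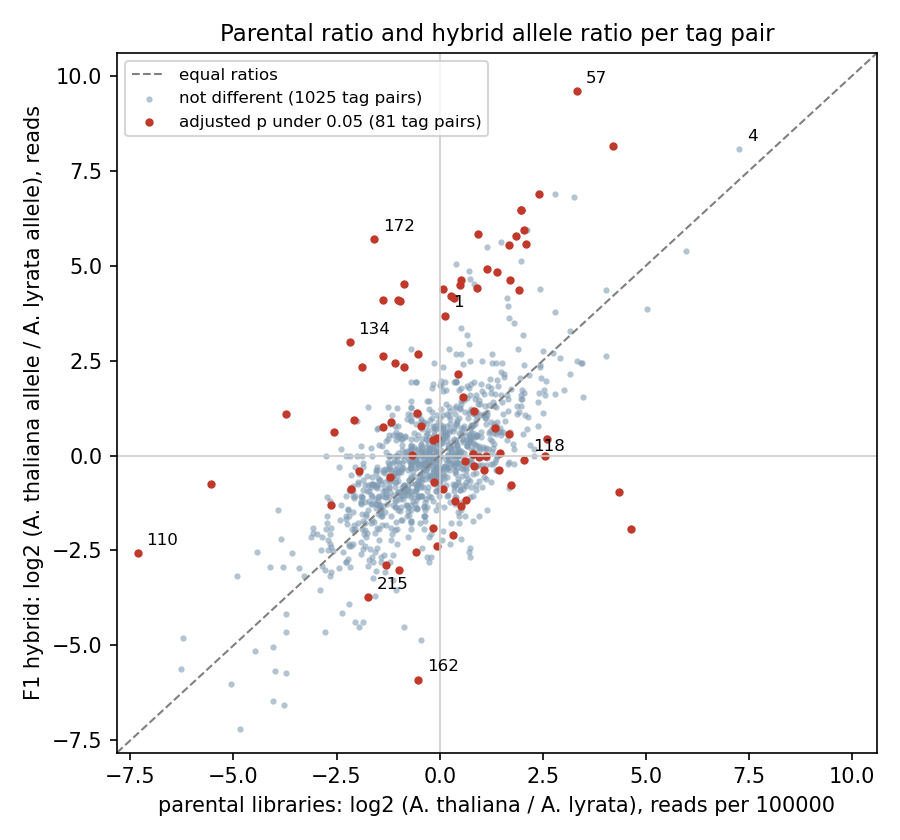
Each point is 1 of the 1106 tag pairs tested, with the log2 ratio of A. thaliana to A. lyrata reads per 100000 in the parental libraries (x axis) and the log2 ratio of A. thaliana to A. lyrata allele reads in the hybrid (y axis). Red points are the 81 tag pairs whose ratios differed, the dashed line marks equal ratios, and numbers name tag pairs of the text; points scatter around the dashed line, with red points mostly above it.

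**Figure D3:**
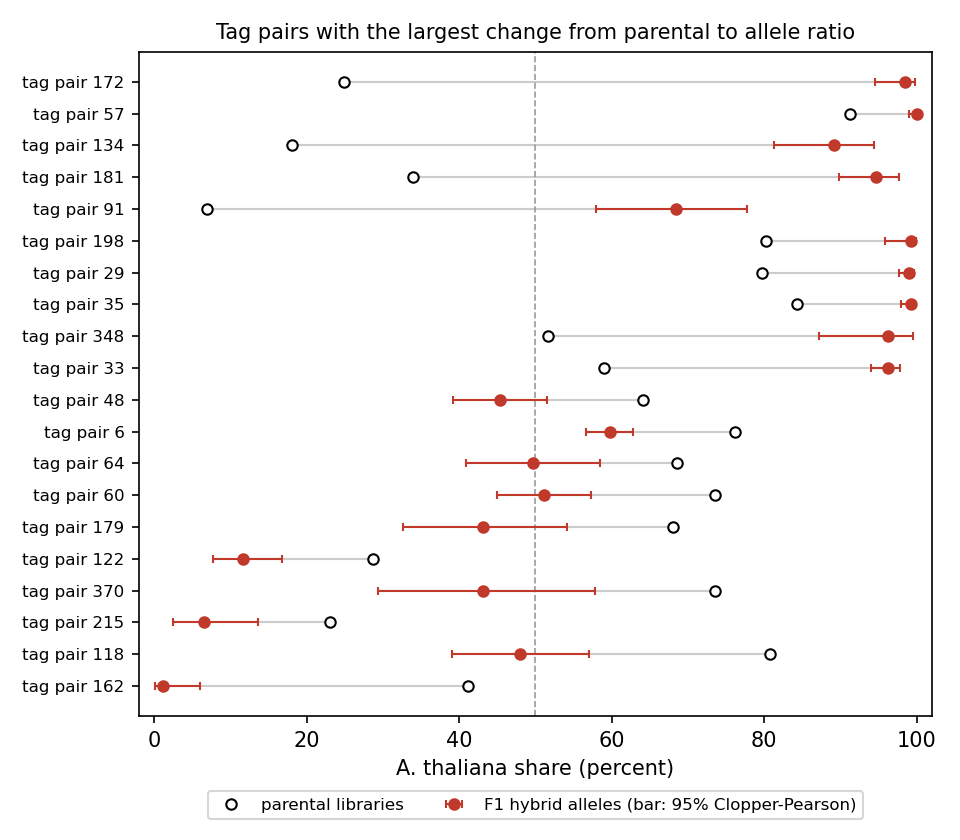
For the 10 tag pairs with the largest move toward A. thaliana and the 10 with the largest move toward A. lyrata, among called pairs with at least 50 assigned reads in the parents and at least 50 in the hybrid, open circles give the A. thaliana share of the depth-scaled parental reads and red circles the A. thaliana share of the hybrid allele reads, with 95% Clopper-Pearson bars of counting error (x axis, percent). Tag pair 172 moves from 24.9% to 98.5% and tag pair 162 from 41.1% to 1.11%.

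Across the 1106 tag pairs tested in both, the log2 ratios had a Pearson r of 0.645 and a Spearman rho of 0.622. Across the 277 pairs with at least 50 reads in both they were 0.738 and 0.754. Tag pairs are not independent replicates. Both contrasts called 174 pairs, and 168 of these went the same way. By the Fisher exact test with Benjamini-Hochberg adjustment, the parental and allele ratios of 81 pairs (7.32%) differed, 51 toward A. thaliana and 30 toward A. lyrata in the hybrid. Centred on the overall allele share, the test gave 96 pairs, 37 toward A. thaliana and 59 toward A. lyrata. The parental ratios in this test were scaled by library totals alone. TMM and median-of-ratios scaling, which moved the median species log2 ratio by 0.24 and 0.30, were not run for it. The median difference of the tested pairs was 0.076, so the calls and their direction may depend on the scaling. Of the 81 pairs, 27 had unequal alleles but no called species ratio, 20 had a called species ratio but no called allele difference, 17 had both in the same direction, 6 had both in opposite directions and 11 had neither. Another 151 pairs had both called in the same direction and no detectable difference between the ratios. With each distinct sequence counted once, 45 pairs differed, and tag pairs 64, 122, 198, 215 and 370 were no longer called. With hybrid reads limited to sequences identical to those of exactly 1 parental library, 53 differed, and tag pairs 118, 134 and 179 were not called. Under this setting the difference of log2 ratios fell from 5.15 to 1.33 in tag pair 134, from 4.84 to 2.33 in tag pair 91, from 4.49 to 2.22 in tag pair 29 and from 4.095 to 2.12 in tag pair 33, and it was 6.52 in tag pair 172.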

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

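All tests of explanations in this part, and the limits that define the pattern of 9 tag pairs below, were chosen after the values were seen, the admixture explanation was narrowed to RNA with the levels of the A. lyrata library after its result was known, and its limits were made stricter and distinct sequences added after the first p was known. The test of the difference between the parental ratio and the hybrid allele ratio singled out 81 tag pairs. Among those with at least 50 assigned reads in the parents and at least 50 in the hybrid, the difference of log2 ratios (allele minus parental) was 7.28 in tag pair 172, 6.27 in tag pair 57, 5.15 in tag pair 134, 5.03 in tag pair 181, 4.84 in tag pair 91, 4.51 in tag pair 198, 4.49 in tag pair 29, 4.48 in tag pair 35, 4.31 in tag pair 348 and 4.095 in tag pair 33. The value of tag pair 57 rests on the pseudocount, because it had no A. lyrata read in the hybrid; with the floor of 3 reads in its place the difference is 3.63, and counting error of the parental ratio comes on top. Toward A. lyrata the difference was -5.38 in tag pair 162, -2.17 in tag pair 118, -2.01 in tag pair 215, -1.82 in tag pair 370, -1.58 in tag pair 122, -1.46 in tag pair 179, -1.40 in tag pair 60, -1.14 in tag pair 64, -1.11 in tag pair 6 and -1.10 in tag pair 48. Of the named pairs with fewer assigned hybrid reads, tag pairs 292, 110, 177 and 105 differed by 4.80, 4.76, -6.59 and -5.32.

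The hybrid library also held reads that matched no tag of either parent. Of its tag reads 10.3% matched none, against 6.30% in A. thaliana and 8.52% in A. lyrata. Among them were 9 clusters of at least 20 reads, with 383 reads in all and 176 in the largest, and the parental libraries had no such cluster. The tags were made from parental clusters of 3 or more reads. The largest unmatched clusters left had 2 reads in A. thaliana and 3 in A. lyrata. The parental libraries are therefore no control for this count.

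In 9 tag pairs with at least 30 assigned hybrid reads and at least 50 reads in the A. lyrata library, at least 90% of the hybrid reads were A. thaliana, and 372 A. lyrata reads stood beside 6694 A. thaliana reads. Wrong assignment does not account for them: 7.20% of the reads of tag pair 1 were A. lyrata, against 0.0298% of held-out A. thaliana reads assigned wrongly (upper limit 0.0521%). A candidate explanation is A. lyrata RNA mixed into the hybrid library. If that RNA had the levels of the A. lyrata library and was the whole source, the 9 pairs would stand at 1 percentage of the A. lyrata level. They ranged from 1.66% (tag pair 172, from 2 reads) to 9.71% (tag pair 36), with a permutation p of 0.0333 on reads (100000 permutations) and 0.284 with each distinct sequence counted once, and the lowest upper limit of a pair, 6.18%, lay above the highest lower limit, 5.91%. Admixture as the whole source therefore cannot be told apart from other sources, because copies of 1 molecule are not independent and no replicate gives the spread between libraries. The mirror case had 2 pairs nearly all A. lyrata, with 5 A. thaliana reads in all, 3.39% of the A. thaliana level, which A. lyrata RNA would not bring. Admixture and real low expression of the A. lyrata copy stay open. So does inheritance of plastids or mitochondria from 1 parent, with the A. lyrata reads from organelles of the other parent or from nuclear copies, because no tag could be placed in a genome here. No biological explanation was tested. Of the 439 A. lyrata tags with at least 50 parental reads, none lacked hybrid reads and none lay below the 5.79% of tag pair 1 after adjustment, but the same was true after adjustment of the 648 A. thaliana tags, 2 of which had no hybrid read. Before adjustment 2 A. lyrata and 6 A. thaliana tags lay below it. A tag near 50 parental reads would have few hybrid reads at that share, so the adjusted count says little about such tags.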

How the results depend on the processing

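The alternatives were set before the data were examined, except 2 that were added after seeing the data, library totals without tag pair 1 and an A. lyrata share taken out of the hybrid. Among the pairs followed, the 20 extreme pairs of each contrast and the 17 pairs with most reads, no ratio called in the main setting changed sign, which for extreme ratios is expected under scalings that move all pairs alike. The 17 pairs held ratios near 0 that did change sign, without a call in either setting, in 8 values of the species ratio, 1 of the hybrid ratio, 7 of the allele ratio and 8 of the difference between ratios. Over all alternatives, fold thresholds included, these 17 pairs lost a call in 7 species, 2 allele and 11 difference values and gained one in 12 species, 9 hybrid, 10 allele and 6 difference values. With both other scalings tag pair 2 lost its species call and tag pair 3 gained one. Among the 20 extreme pairs of each contrast the species calls held in all 217 values, the allele calls in all 230, the hybrid calls in 222, with 14 others that kept their direction but lost the call, and the calls of a difference between ratios in 214, with 17 others that kept their direction but lost the call. The 26 missing values were pairs that an alternative left out of the test. Both other scalings were run for the species and hybrid ratios, but not for the difference between ratios. The counts of calls stayed within 1.5 times of 484, 117, 281 and 81 except as follows. With at least 50 reads, 230 species and 105 allele calls were made, from fewer pairs tested, the median share was 50.5% and r, the Pearson r of the parental and allele log2 ratios across tag pairs, was 0.738; with no read minimum r was 0.552. With each distinct sequence counted once, 72 hybrid calls and 45 differences between ratios were found, and with identical sequences alone 53 differences and an r of 0.786, from 481 pairs. With no fold threshold 232 pairs differed between hybrid and parents. A threshold of 4-fold left 211, 38, 185 and 50 calls by its own construction. Taking 5.79% of the A. lyrata level out of the hybrid treats all A. lyrata reads of tag pair 1 as admixture, without its counting error. This moved the median share to 50% and r to 0.573. It gave 265 unequal pairs (150 to A. thaliana, 115 to A. lyrata) and 96 differences between ratios. Where no construction is named, the cause was not tested. Of the 484 species calls, 408 were also made with TMM factors and 393 with median-of-ratios factors; of the 117 hybrid calls, 98 were made with each. Overlaps were lower elsewhere: distinct sequences kept 66 of the 117 hybrid calls and 45 of the 81 differences, and identical sequences kept 142 of the 281 allele calls and 43 of the 81 differences. At least 3 net differences gave no value for tag pair 172 and 4 other extreme pairs. Nuclear genes alone and the fixed gene lists were not run, since no tag could be given a gene here. No paired analysis was possible because each group has 1 library. The median tag pair had 24 assigned hybrid reads, which limits allele calls to large differences.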

Other observations

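The explanations in this part were tested after the values were seen, except the test of second sequences in the A. lyrata library, whose bounds were written before its result was known. The bound set for the correlations was chosen after exploratory runs, and ties for the most frequent sequence were set to count as no difference after a first result of 1 more A. lyrata pair. Tags without a blastn hit among the tags of the other species, at the settings used, were not part of the comparisons. Lack of a hit does not show that the other species has no similar sequence. Among those with at least 50 parental reads, 167 A. thaliana tags stood in the hybrid at a median of 0.385 times their level in A. thaliana (interval 0.356 to 0.443), and 123 A. lyrata tags at a median of 0.488 times theirs (0.412 to 0.540), on reads per 100000 tag reads. The most read of them, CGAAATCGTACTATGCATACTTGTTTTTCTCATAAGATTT in A. thaliana, had 1150 parental and 551 hybrid reads. The tag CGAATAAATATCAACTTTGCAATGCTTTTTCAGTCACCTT of A. lyrata had 75 parental and 316 hybrid reads, 2.92 times the parental level. The tag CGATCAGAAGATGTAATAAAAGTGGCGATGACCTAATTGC of A. thaliana had 82 parental reads and none in the hybrid. These tags were picked as extremes after their values were seen. The medians rest on tags chosen by their parental reads, which lowers the ratio of hybrid to parent. A tag carried by 1 parental genome alone would also stand lower in the hybrid with no change of expression per copy. The medians therefore do not show a loss of expression in the hybrid.

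Unequal alleles in the hybrid were set against the mean read length of the tags in the parental libraries and against the divergence of the tags. If amplification favoured the allele with shorter reads, the log2 allele ratio would fall with the read length difference. Their Spearman rho across 1134 tag pairs was 0.033 (bootstrap interval -0.025 to 0.091). Read length need not equal the length of the amplified fragment, so the test covers read length alone. If more distant pairs lost reads of 1 allele, imbalance would grow as identity falls, but the rho of its size with percent identity was -0.0064 (-0.064 to 0.051). The hypothesis that the alleles carry the difference between the parents predicts the same direction in both contrasts, and 96.6% of the 174 pairs called in both had it (interval 92.6% to 98.7%). Being called in both contrasts selects for agreement. Of the 369 pairs with a called species ratio, 322 (87.3%) had an allele ratio of the same sign, called or not. An amplification bias by the length of the amplified fragment or by other sequence features would act on parents and hybrid alike and stays open. Wrongly paired tags would also keep their own levels in the hybrid and give the same direction. Agreement of direction cannot tell them from alleles, and they were not tested for.

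Hybrid reads of the A. lyrata allele sometimes showed another sequence than the A. lyrata library. Over the first 60 bases, the most frequent sequence differed in 20 of 305 tag pairs (6.56%, interval 4.05% to 9.95%) for A. lyrata alleles and in 2 of 332 (0.602%, 0.0730% to 2.16%) for A. thaliana alleles. Sequencing errors of the hybrid library would act on both alleles, and the shares differed (two-sided Fisher exact p = 3.03e-05). In 19 of the 20 pairs the hybrid's sequence was also seen at least 2 times in the A. lyrata library. A. lyrata is an outcrossing species, and more than 1 allele in its plant material, with 1 of them passed to the hybrid, may be a source. Of 37 pairs with a second sequence at 25% or more in the A. lyrata library, 17 (45.9%) also had one in the hybrid (interval 29.5% to 63.1%). The range lies below 75%, the bound set beforehand for copies of a gene family, which goes against copies in equal proportions in both libraries as the only source, although counting error alone can take second sequences near the 25% limit below it. In the A. thaliana library 1 pair had a second sequence at that level, against 37 in the A. lyrata library (332 and 305 pairs compared). Copies shared by both species would show in both libraries, so these values argue against shared copies as the main source. The range also passes 50%, the bound set for alleles. That bound is loose, because a single allele passed on would leave no second sequence in the hybrid. The 17 pairs that had one go against a single allele as the only source. Alleles as the source in part of the pairs, copies found in A. lyrata alone with proportions that differ between the libraries, and a mix of both stay open.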
